A study of Homo sapiens with 5 samples.

How the data were processed

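Gene expression was measured in total RNA from human skeletal muscle, taken from the vastus lateralis, a muscle of the thigh. Every title names pool 5 of insulin sensitive muscle, while the descriptions call 2 arrays IS4 and 3 arrays IS5, so that all hold 1 RNA pool is taken from the titles only. RNA was put on 5 Affymetrix oligonucleotide array designs, 1 array each: HuFL, which carries mostly named full-length genes, and Hu35K subA, subB, subC and subD, which carry mostly expressed sequence tags. On these arrays a probe set is a group of short oligonucleotides for one transcript. Other groups of the study are not analysed here, so no comparison between insulin sensitive and insulin resistant muscle was made. With 1 array per design there is no replicate of any gene, no test between samples was run and no p-value is given. The number of people in the pool is not given in the sources used here.

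The values are deposited intensities, one whole number per probe set on a linear scale, and they can be negative. How the authors scaled them, the software and any detection calls are not given in the sources used here. Between 22.9% (HuFL) and 33.2% (Hu35K subB) of the deposited intensities were below 0, as a difference of perfect match and mismatch brightness gives. The mean of each array after trimming 2% ran from 33.9 on Hu35K subB to 197 on Hu35K subA, so the 5 arrays were not brought to one trimmed mean. For this reason raw intensities were not compared between arrays, and each gene was placed by its percentile among the named genes of its own array.

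Probe sets were named through the platform annotation given with the data, and symbols were checked against the RefSeq gene table through gene identifiers, which changed 0 symbols. No genome build is named for the arrays and no coordinates are given. Control probe sets, 59 on HuFL and 77 on each Hu35K array, were set aside, including yeast, mouse and Alu probe sets shared by the Hu35K arrays. Of the other probe sets, 5694 on HuFL had exactly 1 gene symbol, 321 had several and 1055 had none. The numbers with 1, several and no symbol were 7538, 154 and 1165 on subA. They were 5082, 94 and 3671 on subB, 5729, 126 and 2996 on subC, and 5624, 162 and 3065 on subD. Only probe sets with 1 symbol named a gene, which left 4985 genes on HuFL, 5718 on subA, 4298 on subB, 4746 on subC and 4611 on subD. Genes whose level can show the sex of a sample were left out.

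A gene took the value of its highest probe set on an array. Its percentile runs from 0 to 100 among all named genes of that array. For 24 gene lists (493 distinct genes), fixed before the data were examined, the level of a list is the median percentile of its measured genes. Its error is a 95% bootstrap interval over the genes (1000 draws), which covers the choice of genes only. The list's median was placed among 10000 random lists of the same size, matched on the number of probe sets per gene in 3 classes, or 6 classes over all arrays. That placing is a description of this pool, not a test. Lists with fewer than 5 measured genes got none. On all 5 arrays together a gene took its highest percentile.

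The noise SD of an array was the square root of its mean squared negative value, with noise taken as symmetric about 0, and the floor was 3 noise SDs. A lower floor, called the robust floor, took the noise SD from the median absolute negative value, and it was chosen after seeing the data because a few very negative probe sets moved the main floor. Spread between arrays was taken from control probe sets above the floor on every array, as the SD of log2 intensity over the 5 arrays, before and after each array's median over them was subtracted. The ratio of 3 prime to 5 prime probe sets was taken for the control genes GAPDH and ACTB. Spearman's rho compared genes measured on HuFL and on a Hu35K array. It is a correlation across genes, which are not independent replicates.

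The genes named follow a rule set beforehand: the 3 highest of each list on HuFL, for insulin signalling the 10 highest plus 6 genes whatever their value (SLC2A4, INSR, IRS1, AKT2, GYS1 and HK2), the 20 genes with the highest HuFL values and the 5 highest on each Hu35K array, members of the liver, brain, pancreas, epidermis and testis lists above the 90th percentile, and the controls GAPDH and ACTB. Other genes were named after their values were seen, among them genes above a Hu35K floor or the lower HuFL floor, or because HuFL lists them at 0. Alternatives tried were the median over probe sets, probe sets without a suffix for shared or less specific probes, genes above the floor only, the mean percentile, lists without shared genes, other floors, another scaling, each array left out and the arrays described as IS4 left out. Leaving out probe sets listed at exactly 0, and a HuFL floor without its lowest probe set, were added after seeing the data.

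The steps were tested on simulated data. On HuFL (4985 genes), 7.5% of 200 random lists of 20 genes fell above the 95th percentile of the random lists, and 98.5% did when 10 members were drawn from the brightest genes. A simulated noise SD of 100 over 7000 probe sets came back as 99.02, but as 255 after 1 very negative probe set was added. The robust form gave 100.4 with that probe set. A simulated spread of 0.25 on 13 control probe sets came back as 0.26 after centring. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The number of arrays limits the precision, since each value is 1 array's.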

Results

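Total RNA of insulin sensitive human thigh muscle, titled pool 5 on every array, was profiled on 5 array designs, with 1 array per design. The descriptions call 2 of the arrays (subA and subB) IS4 and the other 3 IS5, so whether all hold one pool is not settled. The labels state no purpose beyond the name of the pool. The question addressed here is therefore which transcripts gave signal in this muscle, for which cell types and pathways, and how far the array decides the answer. HuFL carried 7129 probe sets, and the Hu35K arrays subA, subB, subC and subD carried 8934, 8924, 8928 and 8928. All values are deposited intensities of single arrays, so none has a replicate error. Probe sets differ in how brightly they bind, so the order of genes by intensity is not an order of transcript abundance.

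On HuFL, 1055 probe sets (14.8%) were listed at exactly 0, against 19 on subA, 81 on subB, 86 on subC and 27 on subD. Among the named genes at 0 were abundant transcripts of skeletal muscle: ACTA1 (skeletal alpha actin), CKM (muscle creatine kinase), TTN (titin), MYL2 (the slow regulatory myosin light chain) and LDHA (lactate dehydrogenase A). A HuFL value of 0 is therefore given only as listed at 0, and such genes, tied at the 26.5th percentile, stand in the list levels below. Of the 376 distinct list genes measured on HuFL, 71 were listed at 0. Of these, 35 were also on a Hu35K array, where 10 were above the floor of that array.

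**Figure D1:**
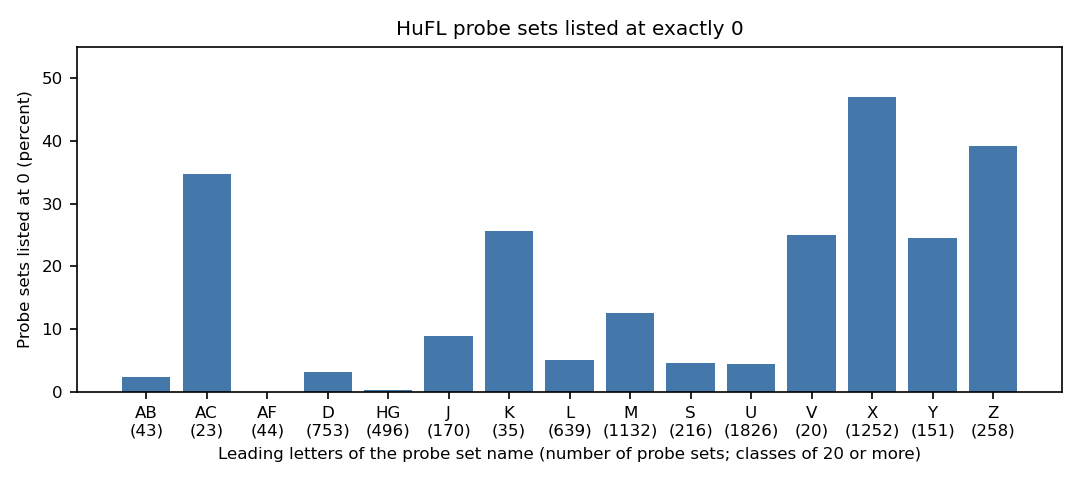
Share of HuFL probe sets listed at exactly 0 (y axis, percent) by the leading letters of the probe set name (x axis, number of probe sets in brackets). Bars reach 47.0% for names with X and 39.1% for Z, and 0.202% for HG.

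The contractile apparatus stood at the top of HuFL. Of 25 measured sarcomere genes, 17 were above the floor of 1248, 3 had a value at or below it and 5 were listed at 0 (ACTA1, ACTN2, MYBPC1, MYL2 and TTN). The median sarcomere gene was at the 99.4th percentile (95% bootstrap interval over genes 94.9 to 99.7), above all 10000 random lists. TNNT1 (slow troponin T) read 14436, TNNC1 (slow and cardiac troponin C) 13739 and MYBPC2 (fast myosin-binding protein C) 13397, and the TNNT1 value rests on a probe set marked as shared or less specific.

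Slow and fast fibre genes were both high. The slow fibre list (6 of 8 above the floor, MYL2 at 0) had a level of 99.5 (68.8 to 99.9), with MYL3 at 10165 on a less specific probe set, beside TNNT1 and TNNC1. The fast fibre list (9 of 11 above the floor, none at 0) had a level of 99.6 (95.6 to 99.9), with ATP2A1, the fast calcium pump of the sarcoplasmic reticulum, at 16035, MYBPC2 at 13397 and MYL11, the fast regulatory light chain, at 12332. Both levels were above all random lists. These lists are not separate from the sarcomere list or others: all 11 fast fibre genes, 7 of the 8 slow fibre genes and 15 of the 25 sarcomere genes also stand in another list. Their intervals overlap, and a comparison of fibre types from different probe sets cannot be made here.

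Of 13 calcium handling genes, 6 were above the floor, 7 were at or below it and none was at 0. The list's level was 93.5 (73.9 to 96.6), above all random lists. Besides ATP2A1, the highest were SLN (sarcolipin, 6503) and PLN (phospholamban, 5892), both small regulators of the calcium pumps. ATP2A2, a calcium pump that is also in the slow fibre list, differed between arrays. It read 202 on HuFL and 87 on subB (on a less specific probe set), below the floor, but 10108 on subD. Set only among the 250 HuFL genes above the floor, the 6 calcium genes had a median at the 52.0th percentile, so they were spread through the detected genes.

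Genes of oxidative phosphorylation and glycolysis were high as groups. For oxidative phosphorylation, 28 of 35 genes were above the floor and CYCS was at 0. The level was 97.6 (96.7 to 98.5), above all random lists. COX7A1, the muscle form of a cytochrome oxidase subunit, read 10968, and the ATP synthase subunits ATP5F1A and ATP5F1B read 8980 and 7236. For glycolysis and glycogen, 12 of 22 genes were above the floor and 5 were at 0 (LDHA, PFKL, PHKA1, PHKB and PPP1R3A). The level of 95.3 (44.3 to 98.3) was above all random lists, with GAPDH at 10052 and ENO3 (muscle enolase) at 8996, both on less specific probe sets, and ALDOA (aldolase A) at 9346.

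The energy buffering list had 4 of 9 genes above the floor and 3 at 0 (CKM, CA3 and SLC25A4). Its level was 88.6 (26.5 to 98.5), at the 99.9th percentile of the random lists, but 57.5, at the 70.2nd percentile, over the 8 genes left when those held by several lists were left out, and 97.3, above all random lists, over the 6 left without those at 0. Myoglobin (MB) read 7772, CKMT2 (mitochondrial creatine kinase) 5557 and AMPD1 (muscle AMP deaminase) 4570. In the TCA cycle list, 5 of 13 genes were above the floor, 6 were at or below it and DLAT and IDH2 were at 0. Its level was 87.3 (77.3 to 97.0), at the 99.98th percentile of the random lists, with MDH1 at 7256, SDHA at 2928 and PDHB at 2912. Of 24 fatty acid use genes, 8 were above the floor, 14 were at or below it and ACAA1 and HADH were at 0. The level was 90.8 (80.1 to 95.1), above all random lists, and the highest members were enzymes of mitochondrial beta-oxidation: HADHB at 4209, ACADM at 4071 and ACADVL at 3897, the last on a less specific probe set.

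Among the 250 genes above the floor, the sarcomere, slow fibre and fast fibre lists kept levels of 92.6, 94.4 and 95. The level there was 68.0 for glycolysis and glycogen, 58.0 for oxidative phosphorylation, 50.4 for fatty acid use and 47.0 for the TCA cycle.

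**Figure D2:**
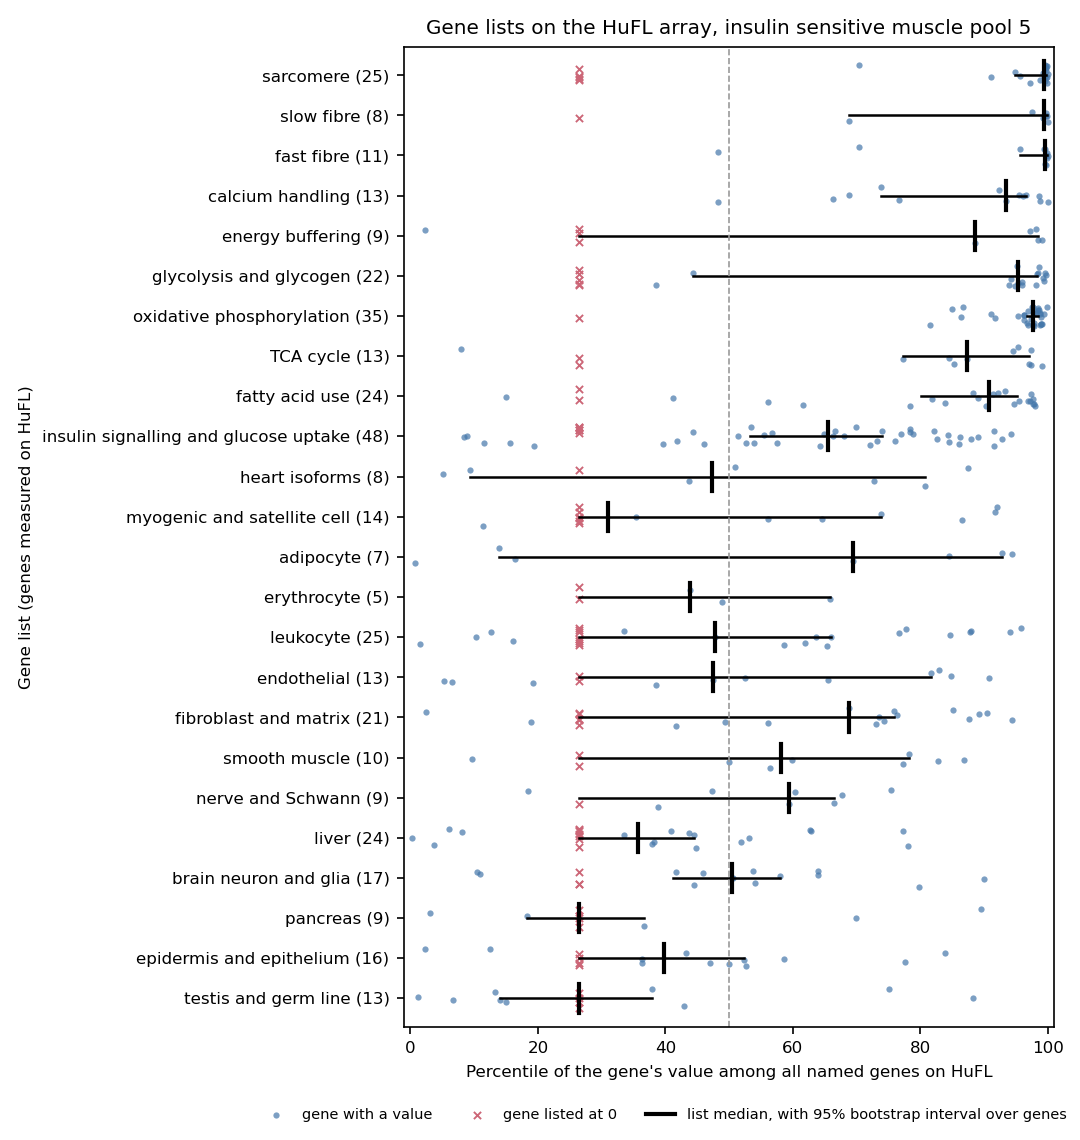
Percentile of each list gene's HuFL intensity among the 4985 named HuFL genes (x axis, 0 to 100) for the 24 gene lists (y axis, genes measured in brackets). Points are genes, crosses are genes listed at 0, tied at 26.5, thick ticks are list medians and horizontal lines their 95% bootstrap intervals over genes. The sarcomere median lies at 99.4, the insulin signalling median at 65.5 and the testis median at 26.5.

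Insulin signalling and glucose uptake genes gave weaker signal. None of the 48 genes measured on HuFL was above the floor, where 250 of all 4985 named HuFL genes were. GYS1 and GSK3A were above the floor of 825 that HuFL has without its lowest probe set, 12 were above the robust floor of 347, and 6 were listed at 0. Both of these lower floors were chosen after seeing the data. The level was 65.5 (53.3 to 74.0), at the 98.7th percentile of the random lists. The 10 highest were GYS1 (muscle glycogen synthase, 1072), GSK3A (914), GRB10 (808), MAP2K1 (802), SLC2A5 (649), SLC2A4 (the insulin-regulated glucose transporter, 586), GRB2 (523), PRKCQ (519), AKT2 (474) and STXBP3 (467). The values of GRB2 and AKT2 rest on less specific probe sets.

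Further genes of insulin action were also below the HuFL floor. IRS1, the insulin receptor substrate, read 412, above the robust floor of 347. The insulin receptor INSR read 87, on a less specific probe set, and HK2, the hexokinase of muscle, 48. On subA, with a floor of 1133 and a robust floor of 431, HK2 read 444 and IRS1 437, both above the robust floor. There INSR read 276, SLC2A4 168 and AKT2 118. On subC, HK2 read 12, INSR 69 and AKT2 106, with IRS1 between the last pair, and on subD INSR 13 and AKT2 226, the last above the robust floor of 178 but below the floor of 463. The IRS1 values on subA and subC, and those of INSR and AKT2 on subC, rest on less specific probe sets. Over all 5 arrays 12 of 58 insulin list genes were above the floor of some array, and the list's level was 80.6 (76.3 to 85.9), at the 99.3rd percentile of the random lists, whose median was 70.9. Of all named genes, 358 of 5718 on subA, 431 of 4298 on subB, 359 of 4746 on subC and 658 of 4611 on subD were above the floor. The share above the floor of some array was not computed for all genes, so such counts, here and for the lists below, show no excess. Signal near or below the floor cannot separate a gene that is off from one that is weakly expressed.

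Lists for other cells of muscle tissue were lower on HuFL than the contractile lists. Only LYZ (lysozyme, 1552, on a less specific probe set) of the 25 leukocyte genes was above the floor. The next were CD3E (1039) and S100A9 (587), also on less specific probe sets. The leukocyte level was 47.7 (26.5 to 66.0), at the 31.2nd percentile of random lists, with 7 genes at 0. Without those it was 59.3, at the 74.8th percentile, but with plain probe sets it was 27.5, at percentile 2.64, so the placing of this list is not settled. CD3E was also above the 825 floor that HuFL has without its lowest probe set. No gene of the fibroblast and matrix list was above the HuFL floor (0 of 21; 1, MFAP4, above the 825 that holds without the lowest probe set), with MFAP4 at 1094, BGN (biglycan) at 723 and SPARC at 651. Its level was 68.8 (26.5 to 75.9), at the 95.9th percentile of random lists, and the 5 genes at 0 were COL1A1, COL1A2, COL3A1, COL6A1 and FN1, collagens and fibronectin. The placing fell to 79.9 with the median over probe sets, 82.5 with the mean percentile and 80.4 on all arrays. It was 98.4 with plain probe sets and 96.4 without genes at 0. On subD, with a floor of 463, COL1A2 (705), DPT (593) and SPARC (590) were above the floor, 3 of 22 genes over all arrays, COL1A2 and DPT on less specific probe sets. The same genes were below the floor elsewhere: COL1A2 on subA (271) and subB (-2), DPT on subC (171) and SPARC on subA (-81).

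The adipocyte list had a level of 69.5 (13.8 to 92.8) over 7 genes, with CFD (adipsin) at 1099, FABP4 at 914 and ADIPOQ (adiponectin) at 475, all at or below the HuFL floor, though CFD and FABP4 were above the 825 that holds without the lowest probe set. Its place among random lists was the 85.8th percentile. CFD (1828) and GPD1 (1316) on subA and PLIN1 (533) on subD were above the floor, 3 of 11 genes over all arrays. The endothelial level was 47.5 (26.5 to 81.7) over 13 genes, with NOS3 at 738, FLT1 at 485 and CD34 at 434. Smooth muscle genes had a level of 58.2 (26.5 to 78.2) over 10 genes, with TAGLN at 546, MYH11 at 428 and LMOD1 at 332. For nerve and Schwann cells the level was 59.4 (26.5 to 66.4) over 9 genes, with L1CAM at 291, MBP (myelin basic protein) at 193 and S100B at 181. These 3 lists stood at the 41.9th, 71.7th and 69.2nd percentiles of random lists, and none of their genes was above the HuFL floor. The nerve placing turned to 31.5 with the median over probe sets, 48.8 with the mean percentile and 29.3 on all arrays, and the endothelial one to 57.7 on all arrays. On Hu35K arrays VWF (697) and CD34 (618) on subD, RGS5 (2235) on subA and MYH11 (1017) on subD were above the floor, VWF and CD34 on less specific probe sets. CD34 was below the floor on subA (393), and RGS5 on subC (233) and subD (282). The Hu35K genes named here and for the matrix, adipocyte, red cell, myogenic, heart, liver, brain and epidermis lists were chosen after their values were seen.

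Red cell genes were few on HuFL. Of 5, HBB and HBD (globin chains) were at 0 and ALAS2 read 176, EPB42 69 and SLC4A1 46. The level was 43.9 (26.5 to 65.8), at the 36.4th percentile of random lists. It was 77.2 (26.5 to 94.3) over 7 genes on all arrays, at the 88.1st percentile of random lists, and 48.9 with the mean over arrays. HBA2 on subC (3677) and ALAS2 on subA (1198) and subD (524) were above the floor, the values on subA and subC on less specific probe sets. ALAS2 was below the floor on subC (321).

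Genes of the muscle precursor program and of heart isoforms gave little signal on HuFL. The myogenic and satellite cell list had 14 genes, none above the floor (CHRNB1 above the 825 without the lowest probe set) and 6 at 0, which include the muscle regulatory factors MYF5, MYF6, MYOD1 and MYOG. Its level was 31.0 (26.5 to 73.8), at percentile 4.33 of random lists, but 64.8, at percentile 76.2, over 8 genes when those at 0 were left out, so the low placing rests on the zeros. The highest were CHRNB1 (an acetylcholine receptor subunit, 849), MEF2C (814) and MEF2A (534), the last pair on less specific probe sets. Above a Hu35K floor were MEF2C (4649 on subD, on a less specific probe set, and 677 on subC) and MEF2D (725 on subB and, on a less specific probe set, 820 on subD), 2 of 16 genes over all arrays. MEF2D was below the floor on subA (850) and subC (218). The 8 heart isoform genes had a level of 47.3 (9.36 to 80.7), at the 34.1st percentile of random lists (54.8th with the median over probe sets and 56.2nd on all arrays), with ACTC1 (cardiac alpha actin) at 574, NPPB at 378 and KCNQ1 at 250. MYL4, at 0 on HuFL, read 2718 on subD on a less specific probe set.

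On HuFL, genes of tissues outside muscle read low. Over the liver, brain, pancreas, epidermis and testis lists, 79 list genes were measured. None was above the floor, 5 were above the robust floor, 22 were at 0, and none lay above the 90th percentile, an intensity of 699. The levels were 35.7 (26.5 to 44.5) for liver, 50.4 (41.2 to 58.0) for brain, 26.5 (18.3 to 36.7) for pancreas, 39.8 (26.5 to 52.3) for epidermis and 26.5 (14.1 to 38.0) for testis. Their places among random lists were percentiles 5.28, 51.3, 6.23, 23.4 and 6.96. The brain placing turned to below the middle in 5 settings: 48.04 with the median over probe sets, 38.04 with plain probe sets, 33.1 with the mean percentile, 26.3 on all arrays and 33.9 without genes at 0.

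The highest values in these lists were GFAP at 697, OMP at 356 and MAP2 at 158 for brain, and SST (somatostatin) at 677, CPB1 at 215 and CPA1 at 14 for pancreas. In the testis list ODF1 read 595, ACRV1 284 and SYCP1 41. In the epidermis list KRT10 read 458, KRT1 321 and KRT5 120. In the liver list APOC3 read 329, FGG 318 and APOA2 151. GFAP, MAP2 and KRT10 rest on less specific probe sets. On the Hu35K arrays, 4 of 16 liver genes were above a floor (AMBP, APOC3, F2 and TTR), as were MAG and SYN1 of 10 brain genes and TGM3 of 8 epidermis genes. Of these 7 genes, F2 (subB) alone was above the floor on a probe set that is not marked as less specific. Several were below the floor on other Hu35K arrays: TTR on subA (-238) and subB (-75), F2 on subA (386), MAG on subA (-72) and SYN1 on subC (-23).

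Of the 20 genes with the highest HuFL values, 9 were in the sarcomere list and 5 encoded cytosolic ribosomal proteins. Besides those given, they were TPT1 (14342), RPL39 (12392), UBB (ubiquitin, 12192), RPS23 (10805), TNNC2 (fast troponin C, 10419), RPL32 (10340), MYH2 (fast 2A myosin heavy chain, 10279), MYH7 (slow myosin heavy chain, 10130), RPS29 (10113), OAZ1 (9989), MYL1 (9927) and RPLP1 (9890). TNNC2, MYH7 and MYL1 rest on less specific probe sets.

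Contractile, ribosomal and mitochondrial genes were also among the highest on the Hu35K arrays. On subA the highest were RPS27 (15792), MYL1 (14737), GAPDH (14115), NDUFA1 (a complex I subunit, 13320) and MYOZ1 (a Z-disc protein, 12816). MYOZ1 was also the highest on subB (5324), followed by CHCHD10 (4031), ATP5MC3 (3780), PDLIM3 (3341) and HSPB7 (3273). On subC they were TNNT1 (9471), CASQ1 (calsequestrin, 6262), CMYA5 (6145), ANKRD23 (5974) and RPS15 (5631). Those on subD were HSPB1 (13540) and HSPB6 (13442), both small heat shock proteins, RPL41 (13000), COX6A2 (11490) and TXNIP (11031). All of those on subC and subD, as well as RPS27, MYL1, GAPDH and ATP5MC3, rest on less specific probe sets.

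With all 5 arrays together, where genes missing from HuFL could enter, 25 of 30 sarcomere genes and 53 of 59 oxidative phosphorylation genes were above the floor of some array. The levels were 99.6 (98.9 to 99.8) for the sarcomere, 99.5 (97.3 to 99.8) for slow fibre, 99.8 (99.6 to 99.97) for fast fibre, 97.2 (90.4 to 99.2) for calcium handling and 98.5 (97.6 to 98.97) for oxidative phosphorylation. Levels were 97.0 (26.5 to 99.1) for energy buffering, 96.3 (93.0 to 99.2) for glycolysis and glycogen, 94.5 (84.4 to 97.0) for the TCA cycle and 92.7 (83.3 to 97.1) for fatty acid use. All 9 of these were above all random lists, though the sarcomere, slow fibre, fast fibre and calcium handling lists share genes. Since a gene here takes its highest of several percentiles, random lists have medians above 50 (59.6 for the sarcomere list).

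The other levels on all arrays were 61.8 for heart isoforms, 41.9 for myogenic genes, 71.5 for adipocyte, 61.9 for leukocyte, 65.5 for endothelial, 74.0 for fibroblast and matrix, 72.6 for smooth muscle and 59.4 for nerve genes. Liver was at 52.4, brain at 54.6, pancreas at 26.5, epidermis at 45.1 and testis at 26.5. Liver, pancreas, testis and myogenic genes lay at percentiles 3.2, 1.92, 0.52 and 2.34 of random lists. With HuFL zeros left out these became 15.8, 4.5, 1.41 and 58.3, and the myogenic level 70.04.

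The share of probe sets above the floor was 5.12% on HuFL (95% Wilson interval 4.63 to 5.66), 4.83% (4.40 to 5.30) on subA, 6.14% (5.66 to 6.66) on subB, 5.30% (4.85 to 5.79) on subC and 9.77% (9.17 to 10.4) on subD. The intervals cover the number of probe sets only. With the robust floor, chosen after seeing the data, the shares were 19.0%, 18.9%, 17.4%, 21.2% and 24.0%. The main HuFL floor rests in part on 1 unnamed probe set at -12623, the next lowest being -2788, and would be 825 without it.

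Control probe sets of GAPDH, ACTB and spiked bacterial genes, present on every array, measured the spread between arrays. Above the floor on all arrays were 13, of which 6 were from spiked bacterial genes and 7 human, the antisense ACTB 3 prime probe set among them. Their median SD of log2 intensity over the 5 arrays was 0.68 (0.61 to 0.71), and 0.22 (0.21 to 0.34) after each array's median was subtracted. Since the IS4 arrays may hold another pool, the spread of the human controls may not be technical alone. Relative to subB, the median control was 1.62 times as bright on HuFL, 2.48 on subA, 1.22 on subC and 2.18 on subD. The GAPDH ratio of 3 prime to 5 prime probe sets was 0.711 ± 0.041 (SD over 5 arrays), from 0.655 on subA to 0.748 on HuFL. For ACTB it was 0.321 ± 0.099 (SD over 5 arrays), with 0.485 on HuFL and 0.242 to 0.332 on the Hu35K arrays, and the ratio of 3 prime to middle was 0.586. The probe sets of one gene differ in binding, so a ratio below 1 is no measure of intact RNA by itself.

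**Figure D3:**
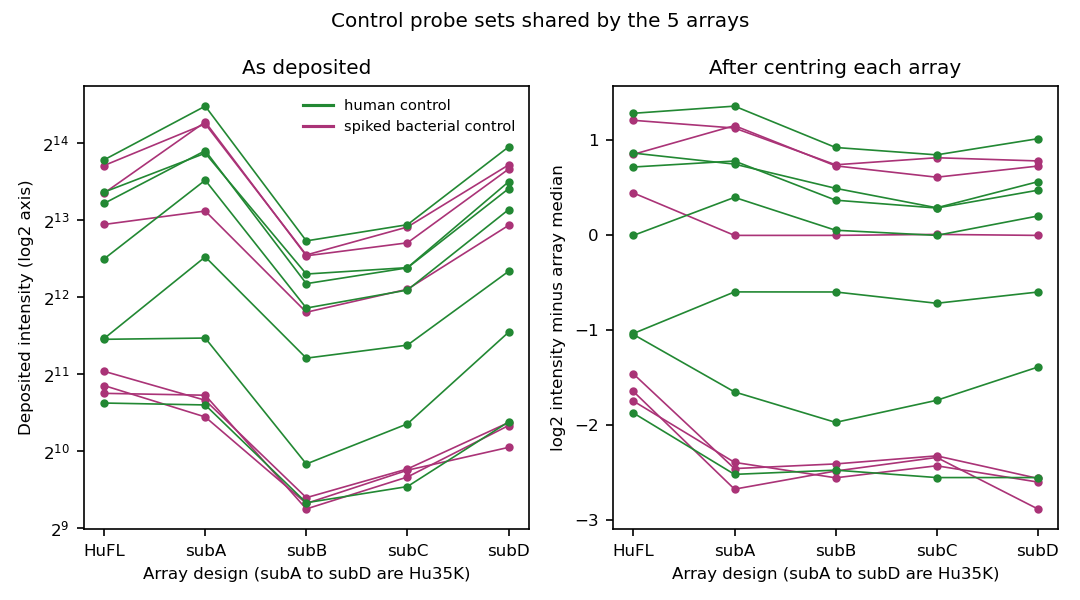
Intensity of the 13 control probe sets on the 5 arrays, as deposited (left, log2 axis) and as log2 intensity minus each array's median over them (right), with human controls in green and spiked bacterial controls in purple. Lines join one probe set over the arrays, and the median SD falls from 0.68 to 0.22.

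Genes measured on both HuFL and a Hu35K array differed widely in rank. Over 2854 such genes Spearman's rho across genes was 0.239 (95% bootstrap interval 0.200 to 0.277), mostly from different probe sets. It was 0.216 with subA alone, 0.126 with subB, 0.238 with subC and 0.235 with subD. The correlation was 0.572 (0.343 to 0.7503) for the 68 genes above the floor on both, and 0.129 for the 1804 genes with probe sets that carry no suffix. For 405 probe sets with the same name on HuFL and subA, and a HuFL value other than 0, it was 0.355 (0.253 to 0.454), though 84 of them alone were above the robust floor on either array, so most lay near background.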

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

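The tests of the HuFL zeros and of array brightness below were chosen after the result was seen, and the test of the IS4 and IS5 labels was planned before.

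Muscle genes such as ACTA1, CKM and TTN were among the 14.8% of HuFL probe sets listed at 0, against 0.213% to 0.963% on the Hu35K arrays, and HuFL stands far from the other 4. Rounding of small values would give about as many zeros as neighbouring whole numbers, but there were 51.7 times as many (1055 against a mean of 20.4). A true absence of these transcripts as a group is argued against by the Hu35K arrays over genes, mostly on different probe sets. There, 357 genes at 0 on HuFL had a median percentile of 59.6, against 48.9 for 360 genes within 30 of 0 on HuFL, a difference of 10.7 (95% bootstrap interval 4.71 to 16.9). The 2497 genes not at 0 had 58.7. Probe sets that share a name with one on subA do not bear this out. There, 60 at 0 had a median percentile of 34.3, against 33.7 for 74 within 30 of 0 and 41.4 for 405 not at 0. True absence of the transcripts is therefore not excluded. On HuFL, however, the 15 unspiked bacterial probe sets read from -263 to 128 and none was listed at 0. As far as control probe sets can show, this argues against absence alone as the source of values of exactly 0. Values missing or set to 0 for a block of probe sets stay open: 43.5% of probe sets with X, Y, Z or V names were at 0 against 5.99% of the others, 7.27 times as many, but these letters were picked after seeing the zeros, and AC (34.8%) and K (25.7%) names among the others were high too. Besides absence of the transcripts, no biological explanation was tested.

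GAPDH, ACTB and the spiked bacterial controls moved together over the arrays. One factor per array may account for most of this, because the SD after centring was 0.327 of that before. Different amounts of labelled muscle RNA would by themselves leave the spiked controls unmoved. Yet the spiked controls ranged over 1.44 on the log2 scale and the human ones over 1.56. For these control probe sets, this argues against muscle RNA amount as the only cause. Whether it adds a part cannot be told: human minus spiked controls ranged over 0.53. No biological explanation was tested.

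The descriptions call 2 arrays IS4 (subA and subB) and 3 arrays IS5, while each title names pool 5, and 2 different RNA pools under one title are a possible explanation. Over the 7 human GAPDH and ACTB control probe sets, that split ranked 5 of the 10 splits into 2 and 3 arrays by mean squared difference (0.040, the highest other being 0.100 for HuFL with subA). These 10 splits are too few to exclude chance, and control genes common to muscle of any pool would show little, so this stays open.

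Of 13 control probe sets tested for an array far from the other 4 after centring, 5 had HuFL apart. Chance alone sets a single value apart in about 1 of 20, but these probe sets share genes and one centring, so the count has no fair chance rate. BioDn 3 prime was itself the median on 3 arrays, which puts it at 0 there by construction. The centred log2 values on HuFL were -1.74 for BioC 5 prime, 0.45 for BioDn 3 prime, -1.46 for BioDn 5 prime, -1.87 for the antisense ACTB 3 prime and -1.03 for the ACTB middle probe set. On subD, 9.77% of probe sets were above the floor, against 4.83% to 6.14% on the other 4 arrays. The gap is smaller with plain probe sets alone (6.45% against 3.58% to 5.36%) and at the robust floor, chosen after seeing the data (24.0% against 17.4% to 21.2%), and subD has the most probe sets marked as shared or less specific (24.5% against 10.4% to 18.4%).

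An antisense probe set of the ACTB 3 prime end gave signal above the brightest unspiked bacterial or yeast probe set on every array. It read 1581 on HuFL, 1554 on subA, 645 on subB, 746 on subC and 1334 on subD, against 128, 341, 114, 165 and 191. Signal above these limits is not particular to ACTB: the antisense probe set of the GAPDH 3 prime end was above them on HuFL (462), subA (554), subB (154) and subD (484), though not on subC (163). Its size beside the sense probe set differed. The ACTB antisense probe set read from 0.447 (subD) to 0.706 (subB) of the sense one. For GAPDH the sense probe set read 5043 (subB) to 14948 (subA), so its antisense signal was a far smaller part. Outside the named genes, 72 of 1055 HuFL probe sets without a symbol were above the floor.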

How the results depend on the processing

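Leaving out probe sets listed at 0, the robust floor and the HuFL floor without its lowest probe set were chosen after seeing the data. No paired analysis was possible because each array design has 1 sample. Signal over background limits these arrays: on HuFL only 250 of all 4985 named genes were above the floor. Most insulin, myogenic and immune genes lie below it, as most named genes do. Beyond the explanations weighed in the section before, causes were not tested.

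Shares above the floor for HuFL, subA, subB, subC and subD were 7.77%, 9.42%, 10.03%, 8.88% and 14.8% at 2 noise SDs and 19.0%, 18.9%, 17.4%, 21.2% and 24.0% at the robust floor. HuFL had 7.88% without its lowest probe set. For subA, subB, subC and subD they were 2.95%, 3.76%, 2.61% and 7.13% with the 99th percentile of negative values, and 4.07%, 5.36%, 3.58% and 6.45% with plain probe sets.

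Of list levels on HuFL, genes above the floor gave sarcomere 92.6, fast fibre 95, calcium 52.0, oxidative phosphorylation 58.0, TCA cycle 47.0 and fatty acid use 50.4. The mean percentile gave sarcomere 83.0, fast fibre 92.0, oxidative phosphorylation 94.0, TCA cycle 75.1 and fatty acid use 78.7. All arrays gave calcium 97.2, oxidative phosphorylation 98.5, insulin signalling 80.6, erythrocyte 77.2 and liver 52.4. Without genes of several lists the sarcomere was at 93.0 (26.5 to 98.7) over 10 genes. On all arrays the mean over arrays gave oxidative phosphorylation 97.4, insulin signalling 61.3, fibroblast and matrix 55.9 and liver 38.5, and without the IS4 arrays insulin signalling was at 76.2. Median and plain probe sets moved 0 of 24 levels on HuFL beyond their intervals, and neither did leaving out zeros (0 of 23), but the intervals are wide. The placing among random lists crossed the middle in 17 of 149 such cases on HuFL, over 9 lists, and 4 of 72 on all arrays. Without zeros, myogenic genes went from 4.33 to 76.2 and leukocyte genes from 31.2 to 74.8 on HuFL. Energy buffering fell from 99.9 to 70.2 without shared genes. Lists with under 5 genes left got no value: 16 among genes above the floor, 2 without shared genes (slow and fast fibre), and erythrocyte without zeros.

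The control spread was 0.53 with arrays scaled to one trimmed mean, and 0.57 to 0.78 as deposited (0.17 to 0.26 after centring) with each array left out. The ratio of 3 prime to middle was 1.05 for GAPDH and 0.586 for ACTB. Leave-one-out ratios of 3 prime to 5 prime stayed within 1 SD. The rank correlation between HuFL and Hu35K was 0.572 for genes above the floor on both, 0.129 for plain probe sets, 0.288 without zeros and 0.126 for subB alone.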

Other observations

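The groups and genes below were chosen after their values were seen.

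Cytosolic ribosomal proteins, which build the ribosome, were high on HuFL outside the fixed lists: 38 of 43 genes were above the floor, with a level of 98.6 (95% bootstrap interval over genes 98.1 to 99.1). Since the group was picked for its bright members, its level is a description only. RPL39 read 12392 and RPS23 10805, and RPL3L, a ribosomal protein of striated muscle, 3296. The 4 members at 0 on HuFL were above the floor elsewhere: RPS27 at 15792 on subA, RPS15 at 5631 on subC, and RPL41 at 13000 and RPS24 at 2244 on subD, all on probe sets marked as shared or less specific. Of all 40 ribosomal protein genes on Hu35K arrays, however, 18 were above a floor, and some genes bright on HuFL read near 0 there, such as RPS29 at 8 and RPL31 at 9 on subC. Small heat shock proteins, chaperones abundant in muscle, had a level of 99.4 (90.4 to 99.98) over 6 genes on all arrays, with HSPB1 at 7410 on HuFL and 13540 on subD, HSPB6 at 13442 on subD and HSPB7 at 3273 on subB, both subD values on less specific probe sets. Of 15 proteasome core subunits on HuFL, 3 were above the floor (PSMA4 at 2303, PSMB6 at 2179 and PSMB5 at 1590), with a level of 93.1 (90.02 to 94.7). The immunoproteasome subunits PSMB8, PSMB9 and PSMB10 read 3, 262 and 544 on HuFL, where another subunit, PSMA5, read 459. On subA PSMB9 read 451, on a less specific probe set.

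The Hu35K arrays held further muscle genes. TMOD4 (muscle tropomodulin) read 9159 on subA, KLHL41 2860 on subB and 6951 on subD, SMPX 2792 on subB, PPP1R3C (a glycogen-targeting phosphatase subunit) 2893 on subB, TCAP (telethonin) 10304 and MYH1 (fast 2X myosin heavy chain, on a less specific probe set) 10121 on subD, and LDB3 2766 on subC. LIM domain proteins of the Z-disc and related ones had a level of 93.4 (63.9 to 99.6) over 12 genes on all arrays but 61.2 (26.5 to 93.5) over 8 genes on HuFL, at the 77.5th percentile of random lists, with PDLIM5 at 8002 on subA and PDLIM7 at 6463 and FHL3 at 5801 on subD, while FHL3 was at 0 on HuFL. On other arrays PDLIM5 read 537 on subC, above the floor, but 323 on subD and 25 on subB, below it. PDLIM7 was below the floor on subA (617) and HuFL (1). Of insulin list genes, 12 were above the floor on a Hu35K array, among them FOXO3 at 1283 on subA, PTPN1 at 1065 on subB, and PPARGC1A at 684 (on a less specific probe set) and CAV3 (muscle caveolin) at 618 on subD. Where another array held FOXO3, PTPN1 or PPARGC1A, the gene was below the floor there. FOXO3 read 202 on subB, PTPN1 256 on HuFL and -148 on subD, and PPARGC1A 80 on subC. GRB10, also of the 12, was above the floor on subC (420) and subD (525), both on less specific probe sets, but below it on HuFL (808). HBA2 (alpha globin) read 3677 on subC, on a less specific probe set. MYL4, an embryonic and atrial light chain, was at 0 on HuFL and 2718 on subD, on a different and less specific probe set.

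Several genes were listed at 0 on one HuFL probe set and bright on another: MYH7 (10130), RPS14 (6479), ACTB (3758), ZNF91 (3045), TLE5 (2513), GATM (2160), ARHGDIB (1366) and DNASE1L1 (1264). Genes at 0 were above a Hu35K floor in 63 of 357 cases, against 22 of 360 genes within 30 of 0. By leading letters of the probe set name, 47.0% of X and 39.1% of Z probe sets were at 0, against 0.202% of HG ones.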
